A study of Homo sapiens with 2 samples.

How the data were processed

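Polyadenylated RNA of the lines MIP101 (5-FU sensitive) and MIP/5FU (5-FU resistant) was sequenced, 1 library each. Per the labels, cDNA was made with random hexamers from DNase-treated RNA, sheared, size selected, amplified by 10 cycles of PCR and read as paired 42-mers or 36-mers. The protocol as described marks no strand, so overlapping genes on opposite strands cannot be told apart. The authors placed reads on features built from Ensembl genes, release 53 per the file names, on genome build hg18 per the labels. The aligner is not given in the sources used here.

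Gene, junction and boundary files as deposited hold raw read counts that the authors did not normalize. All 5 kinds of file hold coverage as deposited, which the authors summed as bases of reads over each feature, and a normalized coverage per base scaled by 1 factor per library. The exon region and transcript files have no read counts, although the design had assumed them. Read equivalents were therefore computed as coverage over the mean bases per read, 40.4 in MIP101 and 39.8 in MIP/5FU. The files hold 36953 genes, 62371 transcripts (54514 with values), 277804 exon regions, 2211260 junctions and 429011 boundaries. Reference tables on GRCh38 gave current gene names and GC content only.

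Gene ratios are log2 of the shares of gene reads after adding 0.5 reads, for genes with at least 100 reads over both libraries, with exact conditional binomial 95% intervals. A gene was counted at 2-fold or more with an interval excluding 0. XIST and the genes on chromosome Y were left out of all comparisons, although the read totals include them. The splicing index is the log2 ratio of a feature minus that of its gene, with a 99.9% interval. It was counted at an absolute value of at least 1, with 50 reads over both libraries for transcripts and exon regions and 20 for junctions and boundaries, in genes with at least 200 reads over both and 10 in each. Features or genes with 0 reads in 1 library are given as a bound against a floor of 3 reads. The limit of their interval nearer to 1 is given beside it and is lower than that bound. The design had set that bound for fewer than 3 reads; for 1 to 3 reads the ratio with its interval is given instead. Apart from this bound and the read equivalents, these rules, the gene lists and the comparisons were fixed before the data were examined.

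Named genes were the 12 highest and 12 lowest protein-coding genes with at least 500 reads over both libraries, UMPS and TYMS, and of each list up to 4 members with the largest absolute ratio. Counts of 5 or fewer were named in full, and DPYD was added after its value was seen. Named features were the 5 highest and 5 lowest in genes with at least 500 reads in each library, up to 10 reciprocal skipping events, the counted features of UMPS, and the largest per gene of the isoform list; exon region 5b of CASP8 was added after its value was seen. List medians were ranked among 10000 random lists matched in 20 bins of expression. Windows of 40 protein-coding genes were set against 1000 shuffles of gene order. Counting error was drawn 20 times from pooled shares. Skipping shares had Clopper-Pearson intervals, and a two-sided Fisher's exact test was used for UMPS reads.

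Alternatives were scaling by the median ratio or by TMM factors, the authors' normalized coverage, other read minima and sizes, the median of features as gene ratio, other windows, and boundaries without EST or mRNA support. The median of features was used only in genes with at least 3 tested features, and the gene's reads were kept elsewhere. Data were simulated from pooled shares with 200 planted changes and counting error only, with no difference between preparations or cultures. All genes at 2.5-fold and above were recovered there with 0 false calls. Among exon regions, 89.6% were recovered at 2.5-fold with 12 false calls, and among junctions 95.5% at 8-fold with 33. Gene reads numbered 200141071 in MIP101 and 109693681 in MIP/5FU. Sequence reads and intergenic or intronic features were not analysed here. Some members of the lists and some features that the naming rule covers are not reported here. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used, and R 4.3.3 with edgeR 4.0.16 for TMM factors.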

Results

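The data are polyadenylated RNA sequencing profiles of MIP101 and MIP/5FU, 1 library of each. MIP101 is a human colorectal cancer cell line derived from a liver metastasis and sensitive to 5-fluorouracil (5-FU), a pyrimidine analog that blocks thymidylate synthesis and enters RNA. MIP/5FU is a clone of MIP101 selected by passage in rising 5-FU, with a 10-fold higher IC50, and was kept in 5 µM drug. Both cultures grew for about 48 hours without drug before RNA was taken. Reads assigned to genes numbered 200141071 in MIP101 and 109693681 in MIP/5FU. Junction reads numbered 24925624 and 13022878, and exon-intron boundary reads 3438984 and 1948334. With 1 library per line, no difference given here has a replicate check, and each interval covers counting error only. Reads from PCR without molecular identifiers are not independent molecules, so true errors are wider. All ratios are MIP/5FU over MIP101, and coordinates are on hg18.

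The first comparison asked which genes differed in level between the resistant clone and its parent. Among protein-coding genes with at least 500 reads, the lowest in MIP/5FU were UBXN10, COL4A1 (a basement membrane collagen chain), OLR1 (the oxidized LDL receptor), ZNF141 and H19. COL4A1 had 2527 reads in MIP101 and 2 in MIP/5FU, 554-fold lower with a 95% interval of 192 to 5721. UBXN10 had 547 reads and 0, 99.93-fold lower against a floor of 3 reads, with a 95% interval from 81.0-fold. H19, an imprinted noncoding RNA that the files type as protein coding, was the most abundant gene in this group, at 8720 RPM (reads scaled by the total of gene reads) in MIP101 and 101 in MIP/5FU. WNT11, a secreted WNT ligand, was 62.4-fold lower (29.2 to 212) and HSD3B1, a steroid dehydrogenase, 52.1-fold lower (29.6 to 114). OLR1 was 128-fold lower (84.0 to 218), and C12orf59, the neighbouring gene on chromosome 12, had a log2 ratio of -5.64, with 8985 and 98 reads. OLR1 spans 10202171 to 10216057 and C12orf59 spans 10222824 to 10235667. ARSE, FUT3 (a Lewis antigen fucosyltransferase), PRF1 (perforin) and C6orf223 completed the 12 lowest, at 38.0-, 36.3-, 34.7- and 27.9-fold lower.

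The highest gene in MIP/5FU was ASRGL1, an asparaginase, with 31 reads in MIP101 and 1326 in MIP/5FU, 76.8-fold higher (54.7 to 115). GIPC2 was 52.7-fold higher (34.3 to 90.5), APLP1, an amyloid precursor-like protein, 23.8-fold (17.5 to 33.9), and VWA5B2 13.9-fold. The basic helix-loop-helix factor ATOH8 was 12.7-fold higher, the Hedgehog effector GLI2 9.65-fold, the guanine exchange factor VAV3 8.91-fold and the RNA-binding protein IGF2BP3 7.98-fold. ACSL4, an acyl-CoA synthetase for long polyunsaturated fatty acids, went from 9.92 to 72.6 RPM, 7.31-fold (6.96 to 7.69). KRT20, an intestinal keratin, was 6.77-fold higher, FBLN7 6.43-fold and MALL 6.40-fold. FUT3, HSD3B1 and ZNF141, like CEACAM6, IFITM1 and the HLA genes below, have close paralogs, so the split of reads among copies is uncertain.

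**Figure D1:**
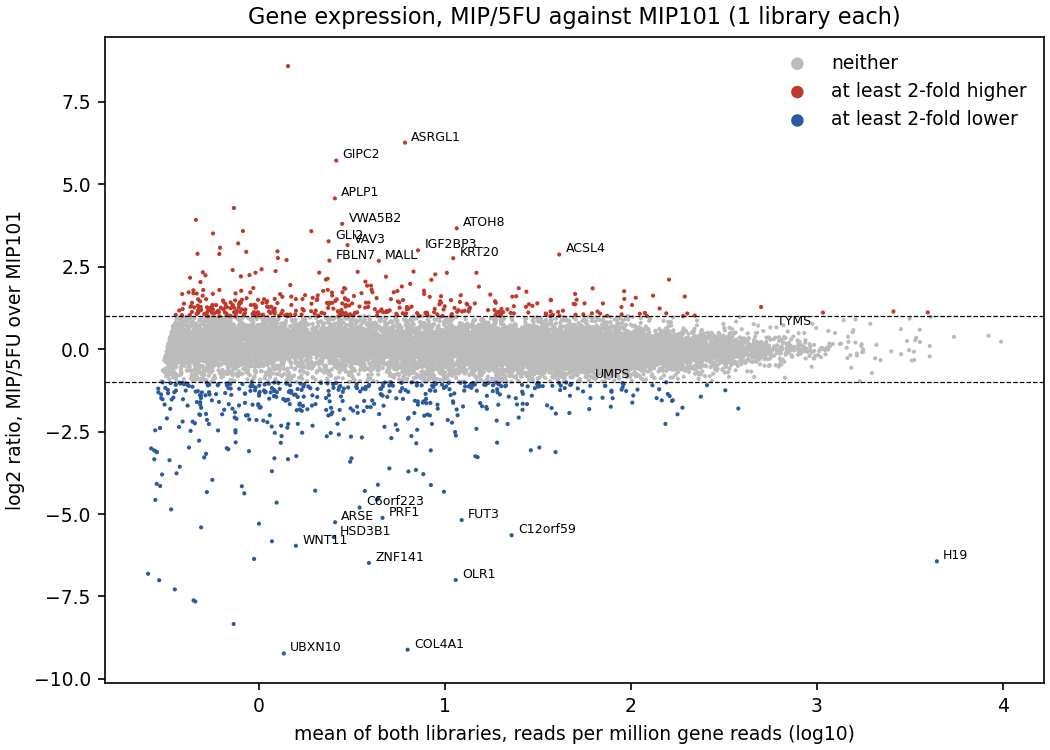
Each point is a gene, with the mean of both libraries in RPM (log10) on the x axis and the log2 ratio of MIP/5FU over MIP101 on the y axis, 1 library each. Red points are the 389 genes counted as at least 2-fold higher and blue points the 475 counted as lower. H19 stands apart as an abundant gene with a low ratio.

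Of 15369 genes with at least 100 reads over both libraries, 389 were at least 2-fold higher in MIP/5FU and 475 at least 2-fold lower, each with a 95% counting interval excluding 0 on the log2 scale. At 4-fold the numbers were 48 and 135, and without a filter on low counts 968 and 858. The median log2 ratio was 0.03, and 83.2% of the genes lay within 1.5-fold. Draws of both libraries from pooled shares never gave more than 1 gene in either direction. The 4-fold threshold moved the higher share of counted genes from 45.02% to 26.2%.

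The genes of 5-FU activation and breakdown were compared next, as the labels concern resistance to this drug. UMPS, which adds ribose phosphate to 5-FU and orotate, was 1.93-fold lower in MIP/5FU (1.867 to 1.996), at 78.4 and 40.6 RPM. TYMS, the thymidylate synthase that 5-FU inhibits, was 1.58-fold higher (1.56 to 1.59), from 436 to 688 RPM. Neither reached 2-fold. CDA, which deaminates cytidine analogs, was 5.58-fold lower (3.32 to 10.8) on 147 and 14 reads. DPYD, the first enzyme of 5-FU breakdown, had a log2 ratio of -0.01. UMPS (identifier ENSG00000114491) lies on chromosome 3 from 125931903 to 125946318 and TYMS (ENSG00000176890) on chromosome 18 from 647619 to 663492.

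None of the 19 tested genes of 5-FU and nucleotide anabolism was counted, with 10 above 0 and 9 below. UCK2 was 1.60-fold lower, and CMPK1 and TYMP 1.54-fold and 1.49-fold higher. The list median was 0.00, at percentile 52.7 among 10000 random lists matched on expression. Of 7 pyrimidine catabolism genes CDA alone was counted, and SAMHD1 was 1.64-fold higher. The list median was 0.11 (percentile 70.5). None of 17 thymidylate and folate genes was counted. MTR, methionine synthase, was 1.73-fold lower and GGH 1.38-fold higher, with a list median of -0.10 (percentile 13.1).

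Among 15 drug transporters, ABCG2 was 4.43-fold lower (4.01 to 4.92) and ABCC5, an exporter of nucleotide analogs, 2.10-fold higher (2.06 to 2.15). ABCC6 was 1.94-fold and ABCC2 1.89-fold lower without being counted. The median of the list was -0.29, percentile 0.28. In base excision and mismatch repair, 0 of 24 genes were counted; SMUG1 and APEX1 were 1.61- and 1.41-fold lower and MUTYH 1.46-fold higher, with a median of -0.14 (percentile 3.21).

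Targets of p53 lay higher in MIP/5FU. Of 27 tested, 3 were at least 2-fold higher and 0 lower, namely CDKN1A at 2.21-fold, GDF15 at 2.14-fold and BTG2 at 2.06-fold; FDXR was 1.62-fold higher. In all, 21 had a log2 ratio above 0, and the median of 0.27 was at percentile 99.94. Of 25 apoptosis regulators, BCL2 was counted, 2.60-fold higher (2.43 to 2.78). APAF1 was 1.69-fold and BMF 1.63-fold higher, CASP8 was 1.51-fold lower, and the median was 0.01 (percentile 51.7). In the cell cycle list CCND2 was counted, 4.31-fold lower, among 38 genes with a median of -0.03 (percentile 34.0). CDKN2B, CDKN2C and E2F1 were 1.77-, 1.57- and 1.52-fold higher.

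Colon epithelial genes moved both ways, with 4 of 29 at least 2-fold higher and 4 lower. CEACAM6 was 11.98-fold higher (7.97 to 19.4) beside KRT20, while the brush border protein VIL1 was 2.34-fold lower and the lectin LGALS4 2.47-fold lower. The mucins MUC2 and MUC13 were also counted as higher, and MUC1 and the nuclear receptor HNF4A as lower. The list median was 0.04 (percentile 61.0). Of 16 mesenchymal genes, 3 were at least 2-fold lower: COL3A1 at 23.6-fold (17.4 to 33.9), SPARC at 2.73-fold and FN1 at 2.01-fold. S100A4 was 1.98-fold lower, and the median was -0.15 (percentile 2.7), or 0.33 over the members with at least 500 reads. Among 13 imprinted genes, H19 and CDKN1C were counted, CDKN1C 6.22-fold lower (5.39 to 7.23). GRB10 and IGF2R were 1.57- and 1.41-fold lower, and the median was -0.23 (percentile 0.88).

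Of 21 WNT targets and intestinal stem cell genes, CD44 was 3.19-fold higher, EPHB3 2.62-fold higher and TCF7 2.65-fold lower, and BMP4 was 1.79-fold lower without being counted. Their median was -0.20 (percentile 1.09). In cholesterol and fatty acid synthesis 0 of 28 genes were counted, while 25 lay below 0. SCD was 1.96-fold, FDPS 1.68-fold, FASN 1.65-fold and ELOVL6 1.63-fold lower, and the median of -0.28 fell below all 10000 random lists. Hypoxia and glycolysis genes had a median of 0.21 (percentile 99.5), with ENO2 at 3.15-fold, ALDOC at 2.17-fold and CA12 at 2.07-fold higher among 29 genes, and SLC2A3 1.88-fold lower.

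Among 29 NRF2 target and xenobiotic genes, AKR1C3 was counted, 2.62-fold higher, in a family with close copies. ALDH3A1 and SLC7A11 were each 1.90-fold higher and AKR1B10 1.90-fold lower, with a median of 0.19 (percentile 99). None of 25 unfolded protein and amino acid stress genes was counted; DDIT3, DDIT4, SESN2 and VLDLR were 1.63-, 1.62-, 1.59- and 1.58-fold higher, and the median was 0.10 (percentile 92.8). Of 31 interferon-stimulated genes, OAS2 was 13.6-fold lower (6.23 to 46.6) on 136 and 5 reads. EPSTI1 was 3.28-fold and IFITM1 2.59-fold lower, IFI6 was 1.92-fold higher, and the median was -0.02 (percentile 22.5). Among 15 antigen presentation genes, NLRC5 was counted, 2.43-fold higher. LRAP, now named ERAP2, and TAP1 were 1.85- and 1.55-fold higher, HLA-DMB was 1.60-fold lower, and the median was 0.28 (percentile 98.8).

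Of 44 splicing regulators 0 were counted. HNRNPD was 1.79-fold, QKI 1.37-fold, RBM5 1.33-fold and U2AF2 1.27-fold lower, and the median was -0.04 (percentile 20.3). Markers of other cell types were scarce. Of 17 hepatocyte markers in the annotation 5 could be tested (median 0.36, percentile 86.1), with HPX counted at 2.09-fold higher and SERPINA1 1.72-fold lower. ALB had 68 reads in each library, 1.82-fold higher as a share of gene reads (1.28 to 2.59). CYP3A4 was 1.28-fold higher with an interval on both sides of 1 (0.891 to 1.82). Of 16 blood and immune markers 4 could be tested (median 0.39, percentile 87.1), of which CORO1A was 2.66-fold lower and CD14, LYZ and ITGAX were not counted. Of 16 endothelial and fibroblast markers 4 could be tested (median 0.16, percentile 61.9): COL3A1, ESAM, PDGFRB and COL1A1. The lists of X-linked cancer-testis antigens and long noncoding RNAs had 1 and 2 tested genes and no median. GAGE1, of a family with near-identical copies, was 1.13-fold higher (0.738 to 1.69), and SNHG5 was 1.26-fold lower.

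**Figure D2:**
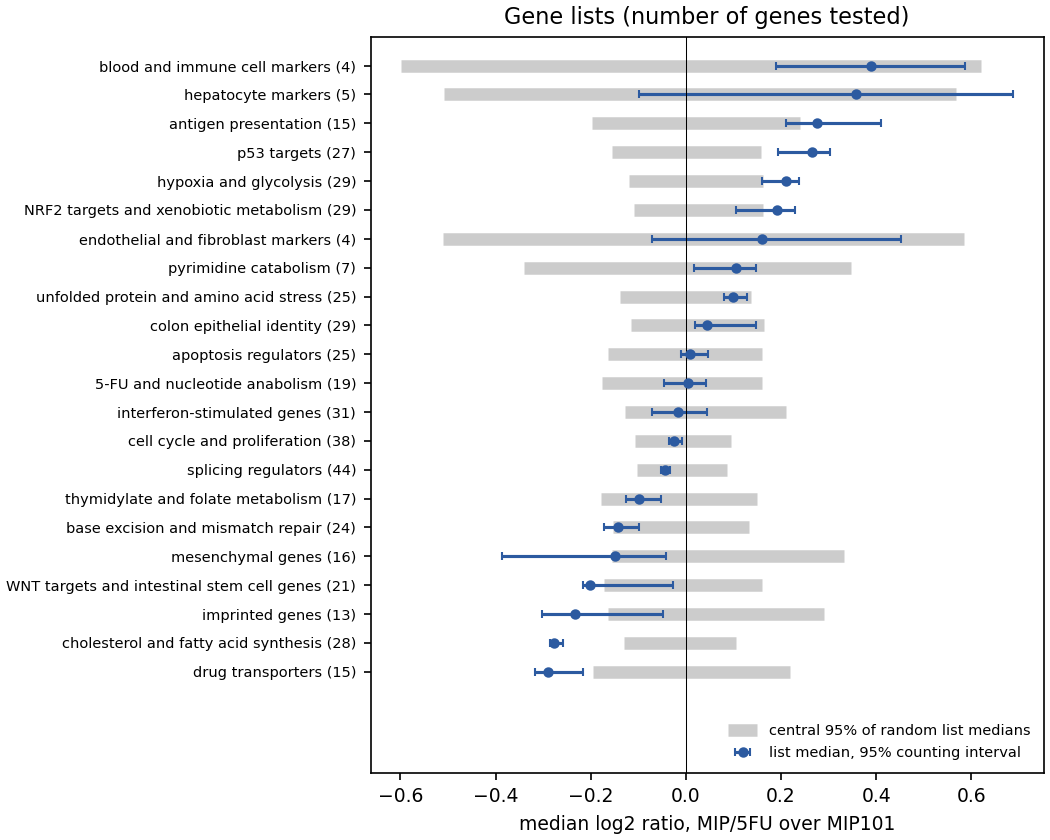
Points are median log2 ratios of MIP/5FU over MIP101 for each fixed gene list, with bars for the 95% counting interval, and grey bands hold the central 95% of random lists of the same size and expression. Medians below their bands are those of drug transporters (-0.29), cholesterol and fatty acid synthesis (-0.28), imprinted genes (-0.23) and WNT targets (-0.20), and above them antigen presentation (0.28), p53 targets (0.27), hypoxia (0.21) and NRF2 targets (0.19).

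Gene ratios were then laid out along chromosomes, since MIP/5FU is a clonal derivative in which segments of the genome can differ. Chromosomes 14, 6, 3 and 4 had the lowest medians, at -0.35, -0.26, -0.24 and -0.22 over 441, 761, 785 and 505 protein-coding genes. Chromosomes 22 and 9 had the highest, at 0.18 each. In windows of 40 consecutive genes, the highest lay at the end of chromosome 3, from LPP to SENP5 (189413415 to 198145977), with a median of 0.83. The lowest lay on chromosome 6 from TXNDC5 to MBOAT1 (7826753 to 20320649), at -0.72. Both lie outside the range of 1000 shuffles of gene order, -0.38 to 0.39. The next highest window, from MCCC1 to TBCCD1 (184215702 to 187767806 on chromosome 3), had a median of 0.67 and holds ABCC5, EPHB3 and VWA5B2.

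Further windows below that range lay on chromosome 14 (from FUT8 to ACOT1 at -0.47 and from NEK9 to FOXN3 at -0.48), on chromosome 1 (SEMA6C to INTS3 at -0.45, TARBP1 to TFB2M at -0.45 and VASH2 to WDR26 at -0.44 among them) and on chromosome 3 (PXK to PROS1, -0.45). Windows above it lay on chromosome 16 (TMEM204 to CCNF, 0.53), chromosome 9 (3814128 to 21549697, 0.53), chromosome 15 (NIPA2 to GOLGA8B, 0.46) and chromosome 7 (TAX1BP1 to CDC2L5, 0.44). The 40 genes around UMPS had a median of -0.34, with 32 below 0, and 2 of them had a lower ratio than UMPS at -0.95. Around TYMS the 40 nearest genes had a median of 0.39, and 37 had a lower ratio than TYMS at 0.66.

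**Figure D3:**
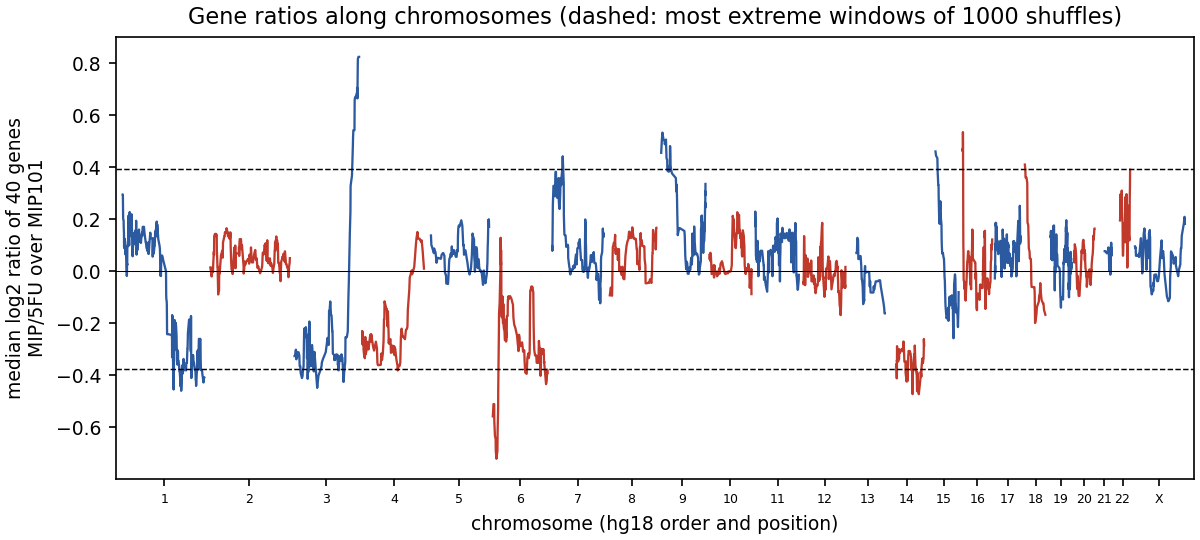
Lines give the median log2 ratio of MIP/5FU over MIP101 in windows of 40 consecutive protein-coding genes, placed by hg18 position, with chromosomes in alternating colours. Dashed lines mark the most extreme windows of 1000 shuffles (-0.38 and 0.39); the end of chromosome 3 reaches 0.83 and the start of chromosome 6 reaches -0.72.

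The series was made to detect alternative expression, so features were compared relative to their genes by a splicing index, the log2 ratio of the feature minus that of its gene. UMPS had the largest reciprocal change when events were ranked by the smaller of the 2 absolute indices. The junction from exon 1 to exon 3, which skips exon 2, had 3 reads in MIP101 and 26 in MIP/5FU, an index of 4.74 with a counting interval of 2.41 to 9.36. The junctions it replaces had 154 and 15 reads (exon 1 to 2, index -1.50) and 243 and 19 reads (exon 2 to 3, index -1.83). Exon 2 itself, 154 coding bases at 125936630 to 125936783 on chromosome 3, had an index of -1.28 (-1.70 to -0.90). The other 5 UMPS exons had indices between 0.00 and 0.23, and none of the junctions joining exons 3 to 6 was counted. The skipping junction joins 125932164 to 125939105. No Ensembl transcript in the files holds it, and 6 mRNAs and 3 ESTs do.

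Skipping reads made up 1.49% of skipping plus mean inclusion reads in MIP101 (Clopper-Pearson 95% interval 0.309 to 4.30) and 60.5% in MIP/5FU (44.4 to 75.02). A two-sided Fisher's exact test of skipping reads against the summed reads of both inclusion junctions gave p = 9.8e-23. An inclusion molecule can count at 2 junctions there, unlike in the shares. The test compares these 2 libraries and not sensitive with resistant cells in general. UMPS was chosen from knowledge of the study, which picked it on these samples, so it is not independent evidence.

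**Figure D4:**
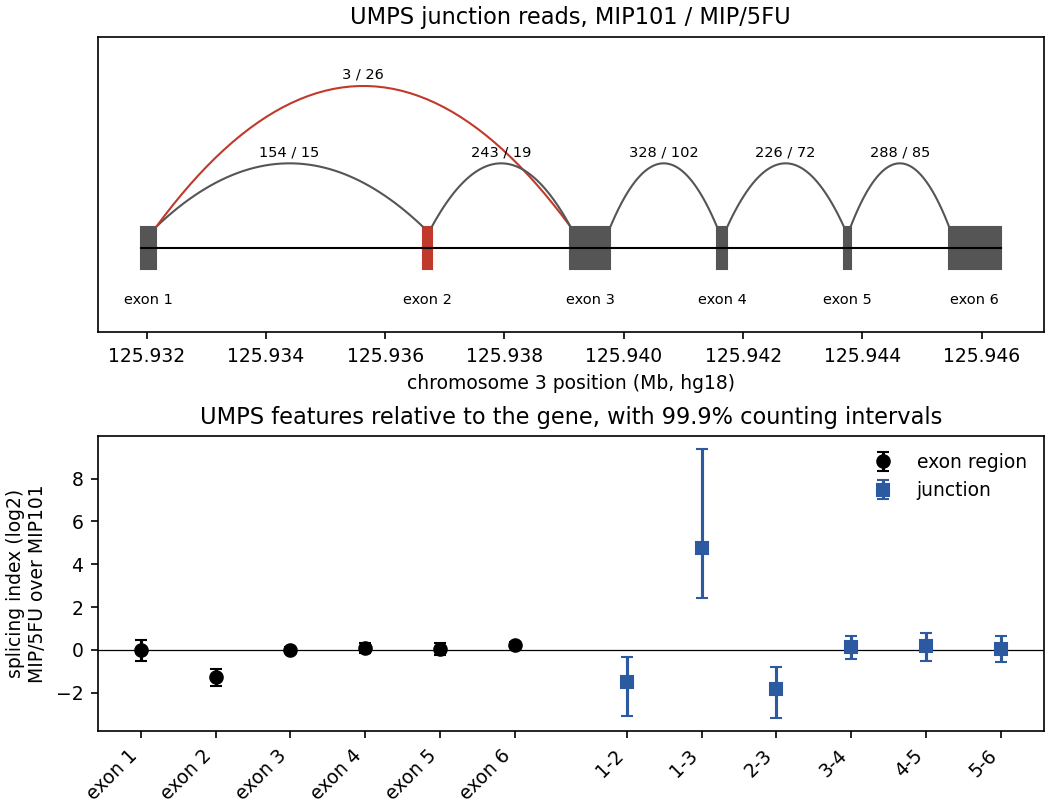
The upper panel maps UMPS on chromosome 3 (hg18, Mb) with exons as boxes, exon 2 in red, and arcs for junctions with their reads in MIP101 / MIP/5FU; the skipping arc reads 3 / 26. The lower panel gives the splicing index (log2) of each exon and junction with counting intervals, where exon 2 and its junctions lie below 0 and the junction of exons 1 and 3 lies at 4.74.

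Besides UMPS, 3 genes had a counted skipping junction with an opposite counted change inside its span. In the files, the skipping junctions of OCIAD1, RAB22A, AP2B1, UBE2M, BUD31, EIF4A2 and UBE2K have 0 Ensembl transcripts, 0 mRNAs and 0 ESTs, unlike that of UMPS. OCIAD1 had 0 and 86 reads on the junction that skips exon 5 (chromosome 4, 48539463 to 48546721), at least 101-fold higher relative to the gene against a floor of 3 reads. Exon 5 of OCIAD1 had an index of -1.07 and its flanking junctions -1.18 and -1.03. RAB22A, a small GTPase, had 38 and 0 reads on the junction that skips exon 4 (chromosome 20, 56352261 to 56361894). That was 8.18-fold lower against the floor (interval from 2.92-fold), with inclusion junctions at 1.21 and 1.12. FAM35A had 47 and 53 reads on the junction that skips exon 7 (index 1.13), with exon 7 at -1.04.

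Of 107276 junctions tested, 61 were relatively higher and 107 relatively lower in MIP/5FU, where counting error alone gave 13.0 and 14.3 on average. Against the median of the gene's junctions instead of its reads, where a gene had at least 3 tested junctions, the split was 95 and 90. All tested junctions had a median index of -0.05. Junction reads came to 12.45% of gene reads in MIP101 and 11.87% in MIP/5FU. Exon-skipping junctions made up 29 of the higher and 29 of the lower calls among 7139 tested, and canonical junctions 32 and 78 among 100137. Of the skipping calls, 10 higher and 12 lower were in Ensembl transcripts, 6 and 10 had only mRNA or EST support, and 13 and 7 had none. In 15 of the 58 skipping calls the junction had at most 3 reads in 1 library, 8 in MIP101 and 7 in MIP/5FU, and 10 of the 15 had no mRNA or EST. In genes with at least 500 reads in each library, the highest after OCIAD1 was AP2B1, an adaptor subunit of clathrin coats. It had 0 and 47 reads, 29.1-fold higher against the floor (interval from 10.6-fold). UBE2M, a NEDD8-conjugating enzyme, followed with 1 and 83 (index 6.69, 3.87 to 18.25), and BUD31, a splicing factor, with 2 and 81 (6.09, 3.72 to 12.40). The lowest was EIF4A2, an RNA helicase of translation initiation, with 229 and 1 (-6.61, -18.16 to -3.84). UBE2K, a ubiquitin-conjugating enzyme, was next with 67 and 0 (14.1-fold lower against the floor, interval from 5.26-fold). In C1orf2, also among the 5 lowest, a canonical junction had 103 and 0 reads (8.71-fold lower against the floor, interval from 3.31-fold). The others were RAB22A and the ribosomal fusion gene FAU with 86 and 1 (-5.18, -16.74 to -2.36).

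**Figure D5:**
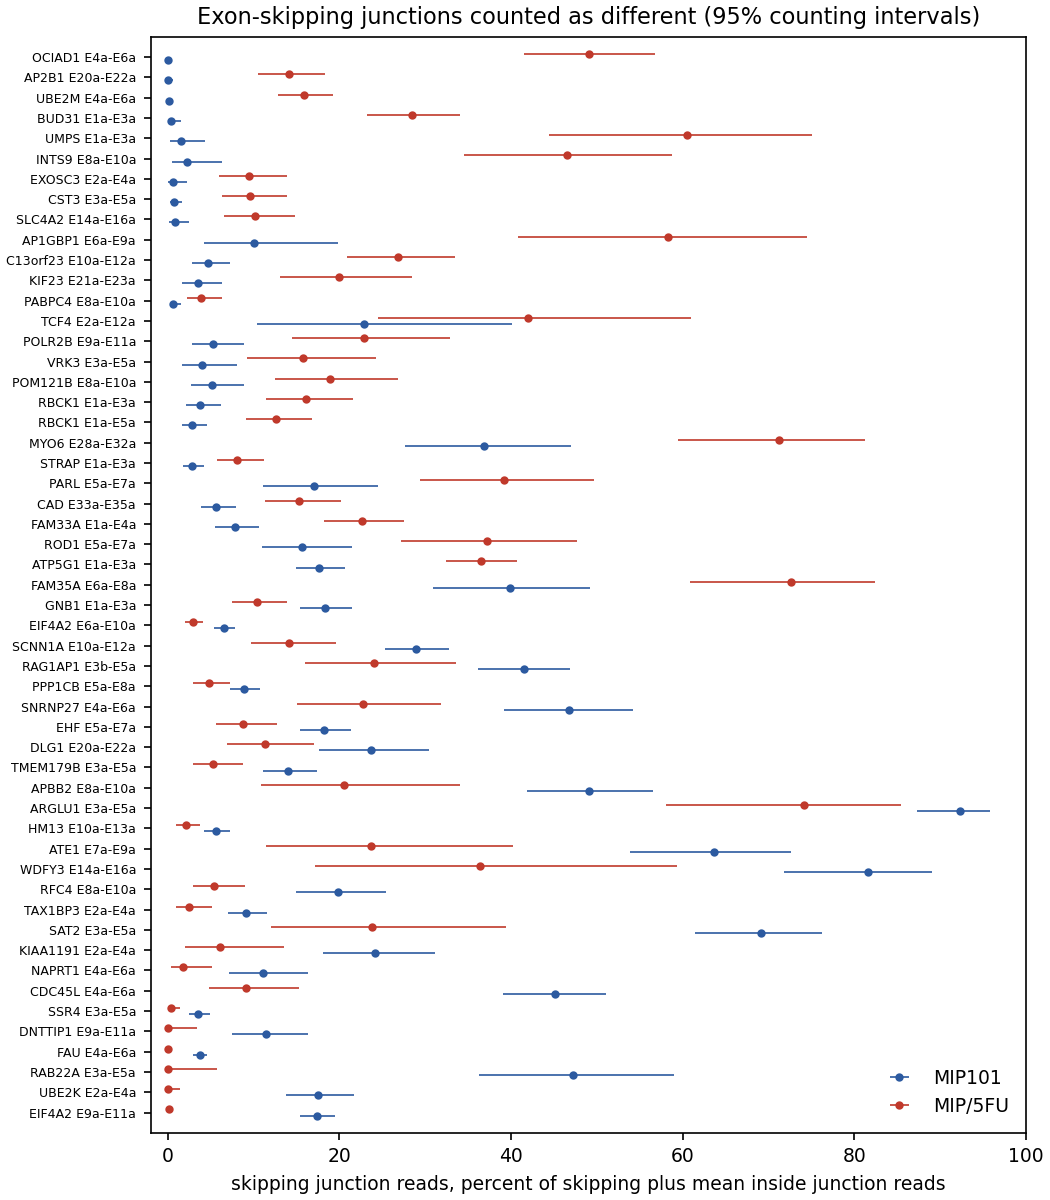
For 53 of the 58 exon-skipping junctions counted as different, those with tested junctions inside the span, points give skipping reads as a percent of skipping plus mean inside junction reads in MIP101 (blue) and MIP/5FU (red), with 95% Clopper-Pearson intervals for counting error. UMPS stands at 1.49% and 60.5%, and OCIAD1 at 0 and 49.1%.

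Of 139845 exon regions, 230 were relatively higher and 156 relatively lower in MIP/5FU, against 4.8 and 7.7 from counting error alone. At an absolute index of at least 2 the split turned to 15 higher and 58 lower. Among genes with at least 500 reads in each library, the lowest were in FBLIM1, a filamin-binding protein, and ACSL5. FBLIM1 had 78 and 0 read equivalents, 7.80-fold lower against the floor (interval from 2.93-fold). ACSL5 had 63 and 0, 7.32-fold lower against the floor (from 2.72-fold). NALP12 (161 and 2, index -5.05, -11.34 to -2.73), SLC41A3 (90 and 3, 11.3-fold lower) and STK32C (51 and 2, 9.36-fold lower) followed. The highest were the first exons of PHLDB2 (3.20, 2.14 to 4.19) and GALNT1 (2.70, 1.61 to 3.99). Next came exon region 1b of RCN2 (2.25), of 20 bases with 16 and 51 read equivalents. Exon 3 of DOK7 (2.18) and the last exon region of CST3, cystatin C (2.14, 1.88 to 2.41), followed. PHLDB2 as a gene had 11459 and 794 reads, so its first exon was kept at 60 and 38 read equivalents while the gene was lower. Of 15227 transcripts, 77 were relatively higher and 31 relatively lower, against 0.65 and 1 from counting error alone.

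The 50 genes of the isoform list, fixed for known cancer-related splicing, included 49 with enough reads, and 6 had a counted feature. Besides UMPS, these were CASP8, with exon regions 3d and 5b at -1.73 and -1.46 and a boundary at 1.12, BIN1 with exon 14 at 1.24, CTNND1 with exon 22 at 1.07, EXOC7 with the junction of exons 1 and 2 at 1.37, and PTBP1 with 3 boundaries, the highest after exon 15 at 2.45. CTNND1 and BIN1 rested on 180 and 257 and on 30 and 46 read equivalents. The EXOC7 junction rested on 23 and 33 reads (interval 0.06 to 2.78). The PTBP1 boundary at 2.45 rested on 6 and 18 reads (0.34 to 5.38).

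Exon-intron boundaries, whose reads cross from an exon into its intron, were counted as relatively higher in MIP/5FU at 236 sites and lower at 39 of 31841 tested. Counting error alone gave 5.9 and 7.4. Genes with several higher boundaries included IMPDH2, the inosine monophosphate dehydrogenase of guanine nucleotide synthesis, with 5, and ACSM3, HNRNPH1, PTBP1, RBM3 and RFC4 with 3 each, chosen after their values were seen. HNRNPH1, PTBP1 and RBM3 encode RNA-binding proteins. Against the median of the gene's boundaries instead of its reads, where a gene had at least 3 tested boundaries, the split was 105 and 80. Changed boundaries enter that median themselves, so their indices can shrink by construction. Boundary reads came to 1.72% of gene reads in MIP101 and 1.78% in MIP/5FU, and the median index was 0.08. Exon regions nearest the 5' and 3' ends of genes had median indices of 0.00 and 0.02.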

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

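The gene total without H19 and the mitochondrial genes, and the recentring of boundaries at their median, were chosen after seeing the data. Without a filter on low counts, 968 genes were higher and 858 lower. With at least 500 reads the numbers were 220 and 299, since fewer genes were tested, and at 4-fold 48 and 135, since the size was stricter. An absolute index of at least 2 left 15 transcripts, 73 exon regions (15 higher and 58 lower), 55 junctions and 77 boundaries, and 5 times the read minimum left 30, 86, 55 and 59. These are stricter rules by construction. TMM factors gave UMPS a log2 ratio of -0.998, and the median scaling gave the thymidylate and folate list a median of -0.131. Both follow from the scaling, which shifts every gene alike, by -0.05 with TMM factors and -0.03 with the median. That shift also puts the medians of all genes (TMM) and of the anabolism and apoptosis lists (median scaling) just below 0, which says nothing about these genes. Boundary reads per gene read were 0.560% in MIP101 and 0.606% in MIP/5FU over boundaries with no EST or mRNA support, and 0.969% and 1.07% as the median over genes with at least 1000 reads. These count other sets of boundaries and genes, and MIP/5FU stayed higher in each. No named gene counted as different changed sign under another scaling or the authors' coverage. Junctions split 95 higher and 90 lower against the median of the gene's junctions, where at least 3 were tested. With at least 500 reads the medians of the mesenchymal and interferon lists turned to 0.33 and 0.07. For the anabolism, pyrimidine catabolism and folate lists, 8 medians under other settings stayed inside their counting interval and 1 moved. For the other lists 38 stayed and 17 moved. Among 111 named genes, 196 of the values under other settings stayed inside their counting interval and 24 moved, by at most 0.16 in log2. With windows of 20 or 80 genes, or at least 500 reads, the highest window stayed on chromosome 3 at 0.73 to 0.88 and the lowest on chromosome 6 at -0.87 to -0.65, each outside the range of 200 shuffles. Recovery of planted changes was lowest for junctions and boundaries. On simulated data a 2.5-fold change was found in 68.7% of junctions and 43.3% of boundaries, against 97.0% of transcripts. No paired analysis was possible because each line had 1 library.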

Other observations

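The tests of counting error and of read placement at skipping junctions, of unspliced RNA, of genes with several boundaries, and of copy number were chosen after at least part of the result they measure was seen.

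The genes in this paragraph and the next were chosen after their values were seen. All 10 mitochondrial protein-coding genes tested were higher in MIP/5FU, from MT-CO1 at a log2 ratio of 0.23 to MT-ND4L at 1.14. The complex I genes MT-ND1, MT-ND3 and MT-ND2 stood at 1.11, 1.11 and 0.98, MT-ND6 and MT-ND5 at 0.77 and 0.59, MT-CYB at 0.92 and MT-CO2 at 0.34. Mitochondrial reads made up 3.63% of gene reads in MIP101 and 5.39% in MIP/5FU.

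LAMA3, the alpha 3 chain of laminin-332, had 34 of 73 tested exon regions relatively lower in MIP/5FU, all within exons 1 to 39, with a median index of -2.17. Its exon 40, where the short transcript starts, stood at 1.29. The long LAMA3 transcript was 3.91-fold lower relative to the gene and the short transcript 2.53-fold higher. In DST, which encodes the cytoskeletal linker dystonin, 15 of 92 exon regions were relatively higher, with a median index of 1.17.

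Exon-skipping junctions that differed, UMPS, OCIAD1 and RAB22A among them, numbered 58, where draws from pooled shares gave at most 7. This excludes counting error of independent reads as the whole cause. The draws held no PCR copies, so they cannot exclude repeated copies of a few molecules. Reads misplaced on skipping junctions with no change of the skipped exon would leave its coverage about as often above as below that of its gene, so coverage was tested with the skipping reads added back to the exon. For junctions higher in MIP/5FU, exons moved the other way in 93.3% of spans with a skipping rate of at least 0.2 of the inside rate (14 of 15, interval 68.1 to 99.8; UMPS, OCIAD1 and BUD31 among them) and in 100% at lower rates (11 of 11, from 71.5; AP2B1 and UBE2M among them), against 54.2% of all tested exon regions, which argues against misplacement as the whole cause. For junctions lower in MIP/5FU the shares were 46.7% (7 of 15, 21.3 to 73.4, or 14 of 15 before reads were added back) and 45.5% (5 of 11, 16.7 to 76.6, or 6 of 11 before), so misplacement stays open for them as a set, although with reads added back the exons of RAB22A (0.59), EIF4A2 (0.19, exon 10) and UBE2K (0.17) still moved the other way and that of FAU (-0.05) did not. At lower rates, RBCK1 (higher, with overlapping spans) and EIF4A2 (lower) each entered with more than 1 span, and the intervals treat all spans as independent. A difference between library preparations was not tested, and a change of exon use between the lines is 1 of the explanations left.

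More boundaries were higher (236) than lower (39) in MIP/5FU, in IMPDH2 and HNRNPH1 among others. The split was 105 and 80 when set against the median of each gene's boundaries, where at least 3 were tested. Genomic DNA in that library was excluded, since boundary reads in genes with few reads were 0.952 times as frequent as in MIP101 (0.943 to 0.961). A few genes with many boundaries were excluded too, as 200 genes had a higher and 39 a lower boundary, a ratio of 5.13. For a rise of unspliced RNA at all genes alike, subtracting the median index of 0.08 left 169 higher and 58 lower. That ratio, 2.91, lay between the bounds set, so a part in the excess of higher calls stays open. Counting error alone gave 5.9 and 7.4 before the subtraction. Some tested boundaries lie inside known mRNAs or ESTs, so such a rise need not shift every index by the same amount. Subtracting 1 median therefore cannot decide whether it is the whole cause. Retained introns in single genes were not tested.

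Gene ratios shifted together along chromosomes, most at the end of chromosome 3 and the start of chromosome 6. After subtracting the trend with transcript GC content the highest window stood at 0.84 and the lowest at -0.68, and with exonic length at 0.82 and -0.75. Both trends were therefore excluded as the whole cause of the highest and lowest windows. The smaller shifts of other windows and chromosomes were not tested in this way. In each window 90% of genes lay on the window's side of 0, but the windows were picked by their medians, so this decides nothing. A change of DNA copy number in the clone and regulation of neighbouring genes together stay open, as DNA was not measured.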
